A study of Gallus gallus with 8 samples.

How the data were processed

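Liver RNA of broiler chickens (Gallus gallus) labelled male and raised at a low or a high stocking density was measured by RNA sequencing. Per the labels' protocols, livers were sampled on day 46, RNA was isolated with a spin column kit, and libraries were sequenced on an Illumina HiSeq. Each of the 8 libraries held equal amounts of RNA from 4 birds of 1 treatment, so the 4 libraries of a group stand for 16 birds. The low density group (A in the labels) had a final target of 24.4 kg/m2 (5 lb/ft2) and the high density group (D) a target of 39.1 kg/m2 (8 lb/ft2).

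The file used here is the authors' deposited table of 1 comparison, D against A. It holds 0 columns of values per library. For each of 23613 Ensembl genes it gives a position, the higher of the 2 group means, a log2 fold change, a signed fold change, a p-value and 2 adjusted p-values, per the file headers. The genome build was GRCg6a, per the submitters' processing notes. The aligner, the counting method, the normalization between libraries and the statistical test are not given in the sources used here. The deposited log2 fold change is D over A, so a positive value is higher at high density, and a power of 2 with this exponent gives the size of the signed fold change. The unit of the deposited group mean is another scale that the header does not name. The deposited means sum to 407974 over all genes, which is too low for a complete per-million scale, so these means served to rank, match and filter genes by expression and, for SELENOP1 and the gene model it overlaps, were added up. The deposited table gives the higher mean alone. It was taken as that of the group favoured by the sign of the log2 fold change, and the lower mean was computed from it and the fold change, which assumes that both are on 1 scale. In 3443 genes every value column is 0, including the p-value, and these were treated as having no result, which left 20170 genes. Of these, 12225 carry a gene symbol in the deposited table (60.6%), and the other 7945 are listed by identifier only. The deposited adjusted p-value is a Benjamini-Hochberg adjustment over all 23613 genes, since recomputing it from the deposited p-values gave a largest difference of 2.4e-05. It therefore counts the genes with no result among the tests.

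Because no values per library were used, no test of the groups was run here, and no SD, leave-one-out result, replicate block or regrouping of the libraries could be computed. The number of reads per library is unknown, and so is the precision that depth gives to any single gene. The planned analysis named count and normalized-value tests first and the authors' own comparison as the last choice, and that last choice applied. A gene was called where the deposited adjusted p-value was under 0.05. Where an implied standard error is printed, it is the size of the deposited log2 fold change divided by the normal quantile of its two-sided p-value. This assumes a Wald test, which the deposited table does not state, so these errors are approximate. None can be given for DIO2, whose p-value is deposited as 0.

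Before the data were examined, 39 gene lists were fixed, 27 of functions and 12 of cell type markers, matched on gene symbol. Apart from the ribosomal protein and proteasome lists, which are name patterns, 700 of the 925 listed symbols had a value. A listed symbol without a match can be an alternative spelling, so this share says nothing about detection. For each list the members called in each direction were counted, over all genes and after a Benjamini-Hochberg adjustment over the list alone. The median log2 fold change of a list was then ranked among the medians of 10000 random lists with as many genes from each of 50 bins of the group mean. A list was said to lie outside the random lists where at most 250, or at least 9750, of the random medians lay below its own. This rank describes the table and is not a p-value. Random lists hold genes that vary independently, so they are too narrow for lists of genes that vary together between animals or libraries. The lists also share some members.

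The ranking was tested on simulated data with the real means of 20170 genes. Lists of 20 unchanged genes fell outside in 238 of 4000 runs (5.95%), against a nominal 5.49% at 400 random lists. Smaller runs, made first and from the same random stream, gave 10 of 100 and 36 of 400 against a nominal 5.19%, and 104 of 1500 (6.93%), so the run was enlarged and the pass limit set from the nominal rate. A list shifted by 0.1 on the log2 scale fell outside in 6 of 50 runs, one shifted by 0.2 in 34, and one shifted by 0.4 in 50. The simulated genes varied independently, with an SD above 0.2 at every mean. Deposited log2 fold changes spread less, with quartiles of -0.11 and 0.08 for genes with a mean of at least 1. These rates are therefore not the power in the deposited data. In a simulation of the adjustment, 199 of 200 genes changed by 6 standard errors were recovered, and 2.93% of the calls were unchanged genes.

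The genes named in the text follow a rule set in advance. It takes the 10 called genes with the largest change in each direction, among genes with a symbol and a mean at or above the lower quartile (0.0584). From each list it takes up to 4 called members with the smallest p-values or, where none was called, the 1 or 2 members with the smallest p-values. The rule covers 82 genes, of which 26 were called, and some of them are not reported here. Members that pass only when adjusted over their list alone are named too, a choice made after their values were seen, and other genes outside the rule are said to be so. Correlations and differences of medians across genes were tested with 100000 permutations, two-sided. Genes of 1 comparison are not independent replicates, so these p-values describe a trend over genes and not a difference between birds. Stricter and looser thresholds, other adjustments and other ways of matching the random lists were run as alternatives. A reference gene table of a later assembly was not used, and positions are those of the deposited table. Python 3.11.15 was used with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.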

Results

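Hepatic gene expression was compared between broilers labelled male and raised to day 46 at a final target density of 39.1 kg/m2 (high density) and at 24.4 kg/m2 (low density). There were 4 libraries per group, each pooling the RNA of 4 birds. The comparison asks whether the liver responds to crowding. All fold changes, p-values and adjusted p-values are those of the authors' deposited table, with positive log2 fold changes higher at high density. That table gives no values per library, so neither the spread between pools nor the number of pools that share a direction is known here. The depth of each library is likewise unknown.

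In the authors' deposited table, 55 of 20170 genes passed an adjusted p of 0.05, and 32 of these were higher and 23 lower at high density. The higher genes included DIO2, the deiodinase that activates thyroid hormone, ANGPTL4, an inhibitor of lipoprotein lipase, and the glycogen-targeting phosphatase subunits PPP1R3B and PPP1R3C. The lower genes included the insulin-like growth factor binding proteins IGFBP1 and IGFBP2 and glutamine synthetase, GLUL. Over the 10867 genes with a mean of at least 1 the median log2 fold change was -0.008, with quartiles of -0.11 and 0.08. An unadjusted p under 0.05 was found for 1126 genes (5.58%), where 1008.5 would be expected with no change. Of the 55 genes, 21 changed at least 2-fold, and the smallest change among them was 0.46 on the log2 scale. The median implied standard error was 0.18 among the called genes. The count fell to 20 at an adjusted p of 0.01 and to 16 after the Bonferroni adjustment.

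**Figure D1:**
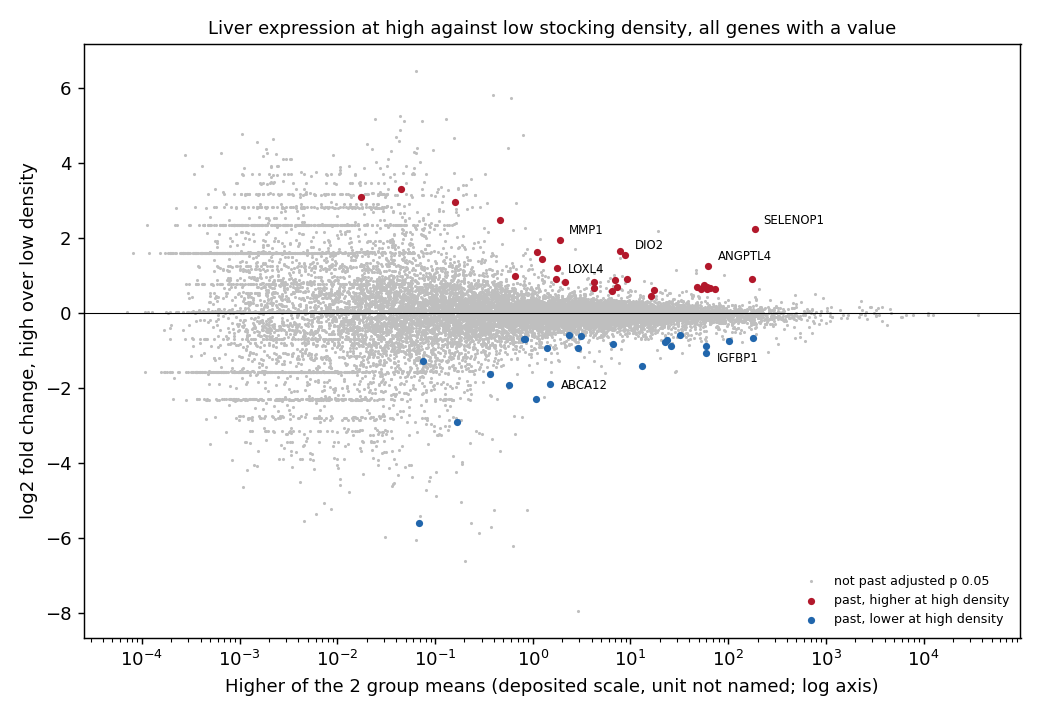
Log2 fold change, high over low density, of the 20170 genes with a value (vertical axis) against the higher of the 2 group means on the deposited scale, whose unit is not named (horizontal log axis). Red points are the 32 genes and blue points the 23 genes past an adjusted p of 0.05 that were higher or lower at high density, and symbols mark the genes among the 10 largest named per direction with a log2 change of at least 1.

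The largest increase among called genes with a symbol was in SELENOP1, which encodes a selenoprotein P (ENSGALG00000047578, GRCg6a chromosome Z, 13587877 to 13593542). Its deposited log2 fold change was 2.24 (4.72-fold, implied SE 0.37, adjusted p = 1.19e-05 in the authors' deposited table). This gene model overlaps another on the same strand, ENSGALG00000014857, whose log2 fold change was -0.52 (adjusted p = 0.73 in the authors' deposited table), and the counting of shared reads is not given in the sources used here. DIO2 (ENSGALG00000026005, chromosome 5, 40752235 to 40769122) rose 2.95-fold, a log2 change of 1.56, and its p-value stands as 0 in the authors' deposited table. ANGPTL4 (ENSGALG00000000619, chromosome 28, 945364 to 954006) rose 2.4-fold, by 1.26 on the log2 scale (implied SE 0.16, adjusted p = 9.18e-12 in the authors' deposited table). The interstitial collagenase MMP1 rose by 1.96 with a wider implied SE of 0.47 (adjusted p = 0.0202), and the lysyl oxidase family member LOXL4 by 1.21 (implied SE 0.21, adjusted p = 2.14e-05), both in the authors' deposited table. The other genes among the 10 largest increases of the authors' deposited table were GADD45G (0.91), PYROXD2 (0.89), HSD3B1 (0.84), PPP1R3C (0.76) and INHBE (0.71). PYROXD2 overlaps another gene model on its strand.

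Among the genes that fell, the lipid transporter ABCA12 (ENSGALG00000003553, chromosome 7, 4266278 to 4345086) had a log2 fold change of -1.88 (3.69-fold, implied SE 0.31, adjusted p = 9.6e-06 in the authors' deposited table). IGFBP1 (chromosome 2, 54916522 to 54922765) had a log2 fold change of -1.07 (implied SE 0.27, adjusted p = 0.0298) and IGFBP2 (chromosome 7, 23255548 to 23307791) one of -0.87 (implied SE 0.16, adjusted p = 0.000138) in the authors' deposited table. The 10 largest decreases in the authors' deposited table also included TENM2 (-0.94), PGAP1 (-0.93), RBPJ (-0.83), CYP4B7 (-0.75), LAPTM4B (-0.72) and GLUL (-0.66). RBPJ encodes the transcription factor of Notch signalling. Of the 33 called genes with a symbol, 7 fell outside the naming rule and are given here after their values were seen. TMEM199, ANKRD9, GLI1, TP53INP1 and STOML3 were higher and AKAP11 and SREK1 lower in the authors' deposited table. The other 22 called genes carry no symbol, 12 of them higher and 10 lower. Picked afterwards as those with the smallest p-values, ENSGALG00000020388 had a log2 fold change of 0.92 and ENSGALG00000051240 one of -1.91 in the authors' deposited table.

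Genes of lipid and sterol synthesis had higher medians at high density. The cholesterol synthesis and uptake list held 13 genes that were higher and 8 that were lower, with a median log2 fold change of 0.05 that lay above 9885 of 10000 random medians matched on expression. Squalene synthase, FDFT1, was the 1 member called, with a log2 fold change of 0.68 (implied SE 0.17, adjusted p = 0.0243 in the authors' deposited table). Adjusted over the list alone, 5 members passed as higher, among them FDFT1, MSMO1, HSD17B7 and STARD4, and 1 as lower, HMGCS1. Of the 18 fatty acid and triglyceride synthesis genes, 12 were higher and 6 lower (median 0.06, above 9910 random medians). None was called over all genes and 2 had an unadjusted p under 0.05. Adjusted over the list alone 1 passed, the triglyceride-forming enzyme DGAT2 (log2 fold change 0.79, adjusted p = 0.0516 over all genes in the authors' deposited table), while GPAM had a value of 0.44 (adjusted p = 0.83 there). Both lists lay within the random lists when these were not matched on expression, above 8243 and 8418 random medians.

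Lipid transport and glycogen genes held several called members without a shift of the list. Among 22 lipoprotein and lipid transport genes, 12 were higher and 10 lower (median 0.01, above 8817 random medians), and 2 rose, ANGPTL4 and the lipid droplet protein PLIN2 (log2 fold change 0.66, implied SE 0.17, adjusted p = 0.036 in the authors' deposited table). Adjusted over the list alone the count was also 2. Of 15 gluconeogenesis and glycogen genes, 9 were higher and 6 lower (median 0.02, above 9015). PPP1R3B (0.64, implied SE 0.15, adjusted p = 0.0101) and PPP1R3C (0.76, implied SE 0.18, adjusted p = 0.0137) rose in the authors' deposited table. PCK1 also passed as higher, and G6PC and PPARGC1A as lower, when adjusted over the list alone. In the growth hormone, IGF and thyroid list, with 11 genes higher and 12 lower (median -0.05, above 1772), DIO2 rose and IGFBP1 and IGFBP2 fell, and the same count of 1 and 2 passed when adjusted over the list alone. In the purine and uric acid list 3 genes were higher and 10 lower (median -0.009, above 6848). GLUL fell (implied SE 0.15, adjusted p = 0.0137 in the authors' deposited table), and adjusted over the list alone XDH, the enzyme that forms uric acid, passed as lower too.

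Circadian clock genes were mostly higher at high density, 15 of 18, with a median log2 fold change of 0.18 that lay above all 10000 random medians. None was called over all genes, and at an unadjusted p under 0.05 there were 7 higher and 1 lower. There were 4 that passed as higher when adjusted over the list alone, PER3, BHLHE40, CRY2 and PER2. PER3 had a log2 fold change of 0.68 (implied SE 0.18, adjusted p = 0.0516 over all genes) and BHLHE40 one of 0.59 (implied SE 0.17, adjusted p = 0.11) in the authors' deposited table. The time of day at which each bird was sampled is not given in the sources used here. Of 20 glucocorticoid-responsive genes, 11 were higher and 9 lower (median 0.06, above 9862, but above 8742 without matching on expression). IGFBP1 was its 1 called member, lower, and adjusted over the list alone PER3, shared with the clock list, passed as higher and IGFBP1 as lower.

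Acute phase and plasma defence genes were higher in 17 of 21 cases (median 0.11, above all 10000 random medians, and above 9704 without matching). Ceruloplasmin, CP, rose (log2 fold change 0.65, implied SE 0.14, adjusted p = 0.0061 in the authors' deposited table), though its model overlaps another on its strand, and LECT2 also passed as higher when adjusted over the list alone. Unfolded protein response genes were higher in 20 of 24 cases by small amounts (median 0.06, above 9961, and above 8835 without matching). None was called, also over the list alone, and 1 had an unadjusted p under 0.05. CHAC1 (0.54) and SDF2L1 (0.22) had adjusted p-values of 0.75 and 1.0 in the authors' deposited table. Cytosolic heat shock genes were higher in 7 and lower in 16 cases (median -0.07, above 506), with 0 called over all genes or over the list alone and 1 with an unadjusted p under 0.05. HSPE1 had the smallest p of the list, with a log2 fold change of -0.30 in the authors' deposited table. HSPE1 and HSPD1, also a member, encode mitochondrial chaperonins, so the list is not purely cytosolic.

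Genes of translation and respiration were lower nearly throughout, by small amounts. Of 66 cytosolic ribosomal protein genes, 64 were lower (median -0.18, above 0 of 10000 random medians). Of 57 nuclear genes of the mitochondrial respiratory chain, 55 were lower (median -0.18, above 0). No member of either list was called, while 13 and 10 had an unadjusted p under 0.05, all of them lower. Adjusted over the list alone, 1 ribosomal protein gene, RPL22L1, and 2 respiratory chain genes, NDUFA1 and ATP5ME, passed as lower. RPL22L1 had a log2 fold change of -0.53 (implied SE 0.15), RPL37 -0.52 (0.17), ATP5ME -0.69 (0.2) and NDUFA1 -0.71 (0.22) in the authors' deposited table. Across the 41 genes of the large subunit, those with higher numbers, which in general name smaller proteins, had lower log2 fold changes (Spearman's rho = -0.80, Pearson's r = -0.64, permutation p = 1e-05, the smallest that 100000 permutations give). Of the 13 mitochondrially encoded genes, 10 were lower (median -0.04, above 5884). None was called, 4 had an unadjusted p under 0.05, and adjusted over the list alone these 4 passed as lower, ATP8, ND4L, ND3 and ND6. ATP8 had a log2 fold change of -0.76 and ND4L one of -0.66 in the authors' deposited table, and each overlaps a neighbouring mitochondrial gene on its strand. The 4 mitochondrial genes under 600 bases had log2 fold changes between -0.76 and -0.54, and the 9 longer ones between -0.09 and 0.02, a split set after the values were seen. Genes with a mean of at least 1 and a span of at most 2682 bases were looked at in the same way, and 678 of the 1040 outside these lists were lower (median -0.083, above 0 of 10000 random medians).

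Marker genes of several blood and liver cell types differed in opposite directions. All 14 T and NK cell markers were lower (median -0.45, above 0 random medians), and GNLY, a cytolytic granule protein, fell (log2 fold change -0.58, implied SE 0.15, adjusted p = 0.0396 in the authors' deposited table). It was also the 1 member passing when adjusted over the list alone. Heterophil markers, of the avian counterpart of neutrophils, were higher in 9 of 12 cases (median 0.60, above all 10000). None was called, and at an unadjusted p under 0.05 there were 4 higher and 1 lower. Adjusted over the list alone 4 passed as higher, AvBD1, CATHL1, CATHL2 and S100A9, and 1 as lower, LYZ. AvBD1 had a log2 fold change of 0.99 (implied SE 0.32) and CATHL2 one of 1.03 (0.39) in the authors' deposited table. The AvBD1 model overlaps 5 others with a value, 1 of them on its strand, and AvBD2 of the same list lies within it on the other strand. CATHL1, CATHL2, CATHL3 and CATHB1, all higher, lie between 4072545 and 4080170 on chromosome 2, and CATHB1 had a mean of only 0.0163. The 9 higher heterophil markers are therefore not all separate cases. Erythroid markers were higher in 12 of 13 cases (median 0.43, above all 10000), with 0 called, 1 passing over the list alone, SLC4A1 (0.67 in the authors' deposited table), and 4 at an unadjusted p under 0.05, 3 of them higher. HBZ, the 1 erythroid marker that was lower, had a log2 fold change of -2.21 at a mean of 0.375 in the authors' deposited table. Cholangiocyte markers were lower in 9 of 12 cases (median -0.26, above 4) and stellate cell and fibroblast markers in 13 of 18 (median -0.17, above 1), with none called over all genes or over the list alone and 3 of each list at an unadjusted p under 0.05. KRT7 (-0.40), ONECUT1 (0.32), POSTN (-0.40) and ACTA2 (-0.25) had the smallest p-values of these in the authors' deposited table. Hepatocyte markers were split, 7 higher and 7 lower (median -0.02, above 7332), with 0 called and 0 at an unadjusted p under 0.05.

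Cell cycle genes were lower in 20 of 30 cases (median -0.16, above 2 random medians), yet the 1 member called, the spindle checkpoint kinase BUB1, rose (log2 fold change 0.70, implied SE 0.18, adjusted p = 0.036 in the authors' deposited table), as it did when adjusted over the list alone. Unadjusted p-values under 0.05 were found for 2 higher members, BUB1 among them, and 1 lower member. Steroid and oestrogen-responsive yolk genes were higher in 5 of 8 cases (median 0.38, above 9886), with 0 called over all genes or over the list alone and 0 at an unadjusted p under 0.05. Without the members of low mean that list lay above 7996 random medians. ESR1 (-0.19) and VTG2 (1.21 at a mean of 0.0188) had the smallest p-values of the yolk list in the authors' deposited table. Genes of the W chromosome, which in birds is carried by females, were looked at after their values were seen and were also mostly higher at high density, 70 of the 92 with a value. All 12 of these with a mean of at least 0.5 were higher (median 0.94), with 0 of the 92 called and 10 at an unadjusted p under 0.05. The sex of the birds in each pool could not be checked without values per library, so a difference in sex between the groups is not excluded for this or any other difference given here. In all, 15 of the 39 lists lay outside the random lists, 6 on the low and 9 on the high side, where 1.95 would be expected for independent genes.

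The remaining function lists lay within the random lists, and no member was called over all genes unless named as such. Fatty acid oxidation and ketogenesis genes were higher in 6 and lower in 15 cases (median -0.06, above 2431), with PDK4 at -0.68 in the authors' deposited table. Glycolysis genes were higher in 5 and lower in 13 (median -0.08, above 1133), amino acid catabolism and one-carbon genes higher in 17 and lower in 12 (median 0.03, above 9734), and antioxidant genes higher in 9 and lower in 17 (median -0.03, above 5588). For xenobiotic metabolism, with 7 higher and 13 lower (median -0.05, above 2997), the 1 called member, CYP4B7, fell (implied SE 0.18, adjusted p = 0.0219 in the authors' deposited table). Bile acid genes were higher in 7 and lower in 7 (median -0.001, above 7154), proteasome genes higher in 11 and lower in 19 (median -0.02, above 4250), and iron handling genes higher in 8 and lower in 5 (median 0.03, above 8825). CP was the called iron gene, and adjusted over the list alone TFR2 passed as higher too. Immediate early genes were higher in 8 and lower in 16 (median -0.06, above 1203), with CYR61 passing as higher over the list alone (0.64, adjusted p = 0.0726 over all genes in the authors' deposited table). Cytokine and pattern recognition genes were higher in 14 and lower in 18 (median -0.04, above 2257) and interferon-stimulated genes higher in 14 and lower in 7 (median 0.03, above 8845), and in both lists the mean had the opposite sign. Hepatocyte markers were the other list whose mean and median differed in sign. At an unadjusted p under 0.05 there were 3 higher genes and 1 lower gene of xenobiotic metabolism, the lower one CYP4B7, and 3 lower genes of fatty acid oxidation, 2 higher and 1 lower of amino acid catabolism, 1 lower of antioxidant defence, 1 higher and 3 lower immediate early genes, 1 higher and 2 lower of cytokine signalling and 1 lower interferon-stimulated gene. Glycolysis, bile acid and proteasome genes had 0.

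The other marker lists also lay within the random lists and held no called gene over all genes or over the list alone. Macrophage markers were lower in 12 of 13 cases (median -0.07, above 1597), endothelial markers in 8 of 14 (median -0.03, above 3040) and thrombocyte markers in 5 of 8 (median -0.09, above 2006). B and plasma cell markers were higher in 8 of 12 (median 0.10, above 8494), skeletal muscle markers in 8 of 12 (median 0.11, above 7123) and pancreas and intestine markers in 7 of 14 (median 0.04, above 6920). At an unadjusted p under 0.05 there were 1 lower skeletal muscle marker, 1 higher pancreas and intestine marker and 0 of the others.

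**Figure D2:**
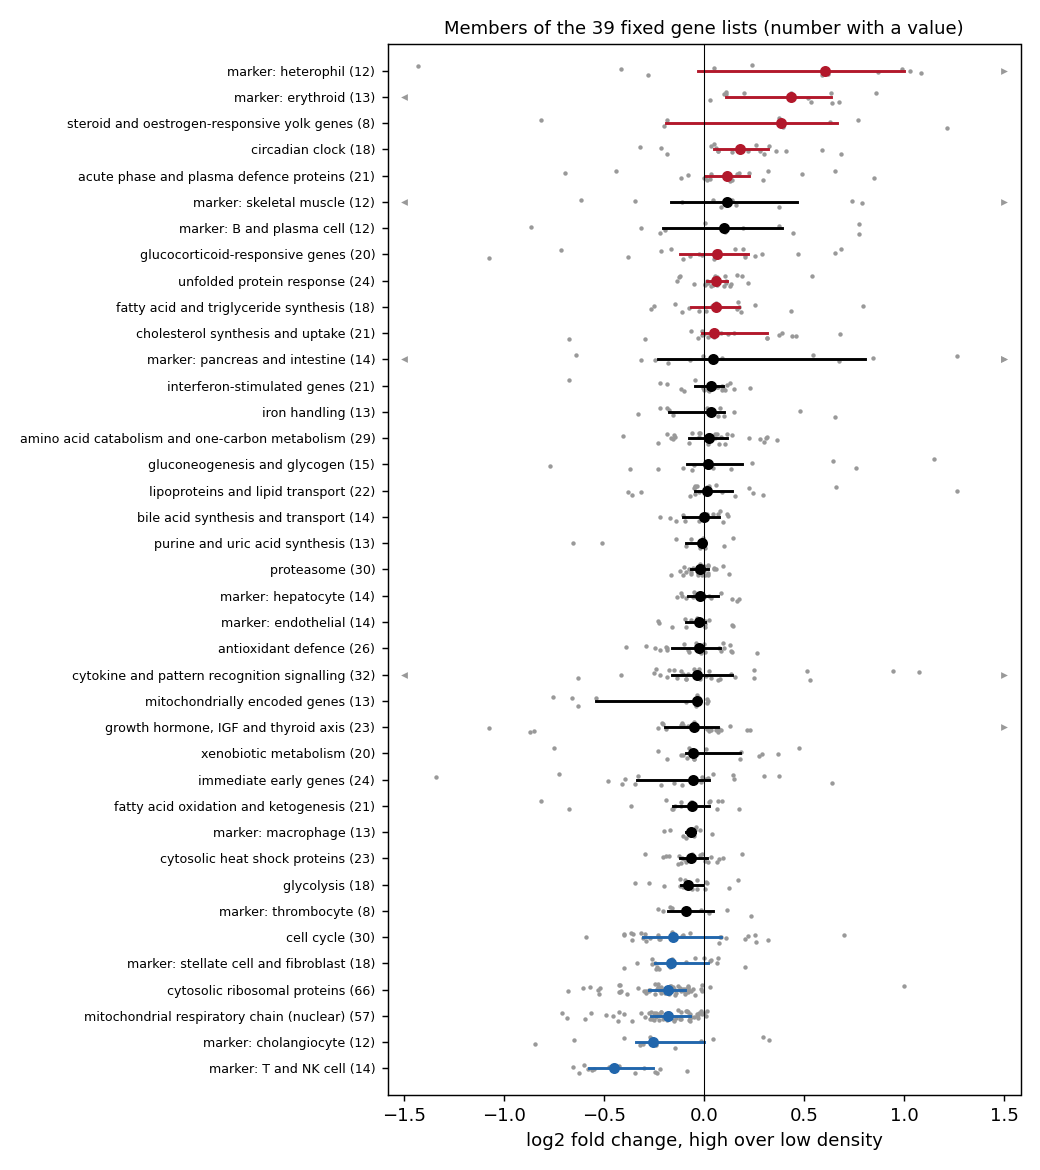
Log2 fold changes, high over low density, of the members of the 39 gene lists, with the number of members with a value in brackets. Grey points are genes, with triangles at the border for values beyond it, large points are medians and bars the quartiles. Blue and red mark the 6 and 9 lists whose median lay outside the random lists on the low and the high side, with T and NK cell markers lowest (median -0.45) and heterophil markers highest (median 0.60).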

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

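The 55 called genes became 20 at an adjusted p of 0.01, 21 where a log2 change of at least 1 was also asked, and 16 after the Bonferroni adjustment, each a part of the 55 by construction. Looser or other adjustments gave 78 genes at an adjusted p of 0.1, 63 when adjusted over the genes with a result, 38 over genes with a symbol (33 of them among the 55) and 72 over genes at or above the lower quartile of the mean (53 among the 55). The deposited fold changes are the same in all of these, so no direction could turn. Among the 82 genes of the naming rule, 17 calls were lost at 0.01 and 18 after Bonferroni, while DGAT2 and PER3 passed under all 4 of the latter settings. Of the 39 lists, 10 lay outside the random lists when these were not matched on expression, 14 without members of low mean, and 14 when also matched on gene span, an alternative chosen after seeing the data. Under that setting fatty acid and triglyceride synthesis lay within, above 9692 random medians. No paired analysis was possible because the table used holds no values per library. For the same reason the planned count tests, other normalizations, filters, pseudocounts, set tests and fits without each library were not run, and regroupings of the libraries could not be counted. Whether 1 pool decides a call, and what depth limits, is unknown.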

Other observations

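Some further groups were looked at only after their values had been seen, and all tests in this part were chosen in the same way. Replication-type histone genes of mean 1 or more were lower in 14 of 15 cases, with a median log2 fold change of -0.25, none called and 2 at an unadjusted p under 0.05, and HIST1H4C had a value of -7.94 (adjusted p = 0.12 in the authors' deposited table). All 15 have spans under the limit of 2682 bases for short genes, and of the 1040 short genes outside the ribosomal protein, respiratory chain and mitochondrially encoded lists, which include these, 678 were lower (median -0.083). Among the 55 called genes, 4 pairs lay within 100 kb of each other, all in the same direction, among them LOXL4 with PYROXD2 and INHBE with GLI1. Another of the 4 is a pair of overlapping gene models without a symbol on opposite strands of chromosome Z. Their log2 fold changes were -5.61 and -2.89 in the authors' deposited table, at means of only 0.0685 and 0.168. The implied SEs were wide, 1.11 and 0.70, so the sizes of these changes are uncertain. The models span 25673879 to 25687313 and 25662511 to 25674252, so most of each model is not shared. Reads in the shared stretch cannot be told apart if strand was not used in counting, and how far they make up both changes is unknown. In 10000 draws of genes matched on expression, 130 gave at least as many pairs, with a mean of 0.865 per draw. That comparison counts all 4 pairs, and none was made without the overlapping pair. LOXL4 starts at 23213501 on the strand of PYROXD2, which ends at 23212431, and whether their reads are separate could not be checked.

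Ribosomal protein, respiratory chain and some mitochondrially encoded genes were lower at high density. An equal fall of the ribosomal protein genes as their only change is argued against. The 19 numbered 10 or lower had a median of -0.08 and the other 47 one of -0.23. The difference was 0.15 (permutation p = 9e-05), although 18 of the 19 were also lower. An equal fall with a further fall of the higher-numbered genes would give the same difference and stays open. The split at number 10 was set after the trend over subunit numbers was seen, so it restates that trend and is no separate test. A loss of short transcripts, in RNA handling or library preparation, is a candidate explanation for the trend. Subunit number and log2 fold change had a rho of -0.80 in the large subunit and -0.62 in the small one (25 genes, permutation p = 0.00116), length and log2 fold change one of 0.77 over the 13 mitochondrially encoded genes (permutation p = 0.00322), and the tenth of other genes with the shortest span (1040 genes) had a median of -0.083, above 0 of 10000 random medians. These tests do not settle it, since the mean also tracked the mitochondrial values (rho = 0.63, permutation p = 0.0235), subunit number and span stand in for transcript length, both nuclear lists stayed above 0 random medians when matched on span, and an effect of density on these genes was not tested apart from it. ATP8 and ND4L, both short, each overlap a neighbouring mitochondrial gene on their strand. ATP6, which ATP8 overlaps, had a log2 fold change of -0.04 in the authors' deposited table. The length of such a gene need not be that of its transcript, and the counting of shared reads is not given. The values of ATP8 and ND4L therefore cannot test a loss of short transcripts. The rho of 0.77 includes both genes and was not computed without them, so it cannot decide the question either.

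T and NK cell markers were lower while erythroid and heterophil markers were higher at high density, among them the globin HBBA (mean 208, log2 fold change 0.64, adjusted p = 0.91 in the authors' deposited table). More blood in the high density livers should raise the markers of blood cells together. The T and NK median minus the erythroid median was -0.88 (permutation p = 0.00031). Both lists were picked after their opposite directions were seen, so this p-value restates that choice. Thrombocyte markers, of another blood cell, were lower in 5 of 8 cases (median -0.09). B and plasma cell markers were higher in 8 of 12 (median 0.10). A smaller share of hepatocytes should raise all other cell types alike. The difference between the T and NK and the heterophil medians was -1.05 (permutation p = 0.00024). These 2 lists were the lowest and the highest of the 39, so this p-value also restates their choice. Macrophage (-0.07) and endothelial (-0.03) medians were below 0 and the erythroid median (0.43) above it, so the other cell types did not rise alike. Hepatocyte markers were split, 7 higher and 7 lower (median -0.02). Either may still contribute in part. Separate changes of each cell type with density, or a few birds in 1 pool, stay open, and neither was tested.

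SELENOP1 was the called gene with a symbol that rose most. A candidate explanation is that reads of 1 transcript were divided differently between 2 overlapping gene models, as a variant or an assignment rule could do. The overlapping model ENSGALG00000014857 had a deposited mean of 543.5, taken as that at low density, and a log2 fold change of -0.52 (p = 0.0137, adjusted p = 0.73 in the authors' deposited table). With the lower mean of each model computed from its deposited higher mean and fold change, the sums of both models were 565.9 at high and 583.1 at low density, a log2 ratio of -0.043, close to the 0 that the division predicts. The sums rest on 1 deposited and 1 computed mean per group, the unit of the mean is not named, and where it is scaled by length they are only approximate, so a change of SELENOP1 itself with density stays open and untested.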
